A study of Sus scrofa with 92 samples.

How the data were processed

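RNA sequencing was done on 92 libraries of pigs of 10 breeds at 60 days of age. Of these, 83 came from 9 tissues (heart, liver, spleen, lung, kidney, psoas major, longissimus dorsi, subcutaneous adipose and ovary) and 9 from mixtures of tissues whose composition is not given. There was 1 library per breed and tissue, and the labels do not say whether tissues of a breed came from 1 animal or whether animals were pooled. The authors deposited FPKM values, fragments scaled to gene length and library total, made with TopHat and Cufflinks 2.2.1 on the Sscrofa10.2 genome according to their notes. The annotation release, options and filters are not stated. Read counts were not analysed here, so the absolute depth of a library and the counting error of a low value are unknown, and the spread between breeds is the only error given. Relative depth was estimated from the most frequent ratio of values between 0.004 and 0.4 FPKM in each pair of libraries, taken as the ratio at 1 read, and ran from 0.719 in ovary of Rongchang to 1.41 in the mixture of Bamei. The values were checked for scale: none was negative, totals per library differed, and no pair of libraries was identical.

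Gene symbols were looked up by gene ID in a separate list of names. Where several gene IDs shared a symbol, the ID with the highest mean was used for naming. Genes of the Sscrofa11.1 reference were matched by symbol. Their chromosome was used, and their synonyms served to match symbols of the gene lists. Raw reads and sequence variants were not analysed here.

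FPKM were scaled between libraries by median ratios, computed anew for the libraries of each fit, so the scaled level of a gene differs between comparisons. Genes at 1 FPKM or more in at least 3 libraries of a fit were kept, and log2 of scaled FPKM plus 1 was analysed with limma 3.58.1 (linear models, moderated statistics with trend and robust options) in R 4.3.3, with statmod 1.5.0 and the package data.table (version 1.17.8). Adjusted p are two-sided limma p corrected by Benjamini and Hochberg, and a gene was called at an adjusted p below 0.05. The breeds were the replicates. Loading and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

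The comparisons, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. A gene was called for a tissue class when it was higher than in each of the other 7 classes, with the largest of the pairwise p adjusted over genes below 0.05 and every log2 difference above 1. Psoas major and longissimus dorsi formed the class skeletal muscle, and breed was a block. Psoas major was compared with longissimus dorsi in 10 breeds, and heart with the mean of both muscles in 9 breeds, with breed as block. Breeds were grouped by origin, Western or Chinese, from general knowledge. Origin was compared on the mean log2 level over 8 tissues, lung left out because Rongchang has none, in 9 breeds, and within each tissue in all breeds that have it. A moderated F test asked whether the tissue profile differed by origin, and a moderated t test whether the psoas minus longissimus difference did. Each mixture was compared with the mean of the 9 tissues of its breed in the 8 breeds that have all of them. Similarity of libraries was measured by Spearman correlation over genes, and shares of variance by sums of squares per gene.

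Gene lists, 42 in number, were written from general knowledge before the data were examined. They cover tissue and cell type markers, muscle fibre types, energy and lipid metabolism, development, immune cells and responses, stress, cell division, matrix, translation and the clock. Of 866 listed symbols 562 were matched. Lists with at least 5 tested genes were tested with camera, preset correlation 0.01, and again with the correlation estimated per list. Counts of members that pass are given as adjusted over all genes and as adjusted over the list alone.

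Named genes follow a fixed rule, limited to genes with a symbol. Per tissue class, the 6 called genes with the largest smallest log2 difference were named. For the muscles, heart and mixtures, the 12 called genes with the largest log2 difference in each direction were named, with the same sign in at least 9 of 10 breeds. For origin over 8 tissues up to 12 per direction were named, for single tissues the 5 with the smallest p, for the tissue profile the 10 with the smallest p, and per list up to 4 members that pass or the 2 with the smallest p. Some genes that the rule names are not reported here.

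Alternatives were FPKM as deposited, quantile normalization, a pseudocount of 0.1, no filter, a filter at 5 FPKM, leaving out each breed, no block, moderation without trend and robust options, a log2 difference above 2 for tissue genes, an estimated correlation per list, all tissue libraries with a within-breed correlation, leaving out Tibetan wild boar, Pearson in place of Spearman correlation, and the mean of log2 values as reference for the mixtures. Chosen after the data had been seen were leaving out genes with conflicting zeros, the Meishan ovary, the Meishan subcutaneous adipose library, or genes called in liver. A conflicting zero is a gene listed at 0 in a library and at 100 FPKM or more in another of the same tissue. Such genes were kept, and a fold is not given against a group listed at 0.

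Most of the tests were run on simulated data with known changes, by origin within a tissue in liver and spleen alone, and for gene lists between the muscles alone. Fold changes of 1.5, 2 and 4 were recovered for 73.1%, 97.0% and 100% of genes between the muscles, for 82.1%, 98.5% and 100% between heart and muscle, for 62.7%, 94.0% and 95.5% by origin over 8 tissues, and for 23.9%, 73.1% and 92.4% of tissue profiles by origin. All simulated changes were set in genes with a mean level well above the filter of 1 FPKM. The shares recovered, here and in the results, therefore do not cover genes at low level. Of 10 simulated lists raised 1.5-fold between the muscles, 10 were recovered, and 0 of 10 unchanged lists were called. Members of these lists varied independently, so the rate of false calls for lists of genes that vary together is not known from them.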

Results

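RNA of pigs of 10 breeds, sampled at 60 days of age, was sequenced in 92 libraries. Single tissues made up 83 of them: spleen, psoas major and longissimus dorsi had 10 libraries each, heart, liver, kidney, subcutaneous adipose and ovary had 9 each, and lung had 8. The other 9 libraries were mixtures of several tissues of 1 breed, with a composition that the labels do not give. Berkshire, Hampshire, Landrace, Large White and Piétrain are Western breeds, and Bamei, Jinhua, Meishan, Rongchang and Tibetan wild boar are Chinese pigs. Rongchang had no lung library, and Tibetan wild boar had spleen and both skeletal muscles alone. Every tissue of a breed was measured in 1 library, so the breeds are the replicates of a tissue. Gene expression was given as FPKM for 25322 gene IDs, of which 11804 carried a gene symbol. Read counts were not analysed here and the absolute depth of each library is unknown. Total FPKM ranged from 519075 in psoas major of Tibetan wild boar to 2196140 in heart of Large White, and 10175 to 14561 genes reached 1 FPKM in a library. Some abundant transcripts were listed at 0 where the tissue is known to make them: ALB, the main plasma protein of the liver, was at 0 in 9 of 9 livers, and ACTA1, skeletal muscle actin, was at 0 in 9 of 10 longissimus dorsi libraries. In all, 276 genes were listed at 0 in a library and at 100 FPKM or more in another library of the same tissue, and 43 of these had a symbol.

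The first comparison asked how far tissue and breed set the expression profile. For 67 of the 83 tissue libraries the most similar other library was of the same tissue, by Spearman correlation over genes. All 16 exceptions paired psoas major with longissimus dorsi of the same breed. Tissue accounted for a median of 83.2% of the variance of a gene and breed for 4.10%, over 16996 genes in the 72 libraries of 8 tissues and 9 breeds. Simulated data with tissue effects and no breed effect gave 1.41% for breed. The lowest median correlation with the own tissue was 0.911, in the Meishan ovary.

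Each organ carried its own set of transcripts. Of 17207 genes tested, 220 were higher in heart than in each of the other 7 tissue classes, 782 in liver, 460 in spleen, 299 in lung, 479 in kidney, 375 in skeletal muscle, 288 in subcutaneous adipose and 1047 in ovary. On deposited FPKM the counts moved to 487 in liver, 212 in skeletal muscle and 1773 in ovary, and with a log2 difference above 2 they fell to between 86 in heart and 400 in liver. In heart, TNNT2, the cardiac troponin T of the thin filament, reached 5310 ± 687 scaled FPKM (SD, n = 9) against 14.5 ± 11.5 (n = 20) in skeletal muscle, the nearest class. MYBPC3, cardiac myosin binding protein C, was at 754 ± 160 and NEBL, a nebulin of cardiac Z discs, at 220 ± 34.9 in heart. CCK, known as a gut and brain peptide hormone, was at 738 ± 359 in heart and at 0.538 ± 0.296 (n = 10) in spleen, its nearest class. KCNJ4, an inward rectifier potassium channel, was at 121 ± 47.1 and SERPINB2 at 78.5 ± 31.0. Of 9 heart markers, 7 were called in heart.

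Liver was marked by transcripts for plasma proteins. AHSG, a plasma glycoprotein, was at 15898 ± 8065 scaled FPKM in liver (SD, n = 9), AMBP at 5975 ± 1457, HPX, the haem carrier hemopexin, at 4890 ± 1385, FGB, the fibrinogen beta chain, at 3763 ± 2399 and APOA2 at 3284 ± 644. CYP2E1, an enzyme of ethanol and drug oxidation, was at 1963 ± 515. The nearest class for all 6 was subcutaneous adipose, where AHSG was at 16.4 ± 12.4 and CYP2E1 at 1.98 ± 1.30 (n = 9). Liver carried 16 of 18 liver markers, 9 of 10 genes of drug metabolism and 10 of 18 genes of cholesterol synthesis, such as MVK at 93.4 ± 36.6. The other 2 liver markers were CYP7A1, called in lung, and ALB, called in subcutaneous adipose at 67.7 ± 45.3 because the liver values were all listed at 0.

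Spleen was marked by transcripts of lymphocytes. SPIC, a transcription factor of red pulp macrophages, was at 223 ± 30.5 scaled FPKM in spleen (SD, n = 10) and at 1.03 ± 0.592 in subcutaneous adipose (n = 9), MS4A1, the B cell antigen CD20, at 77.7 ± 13.8, GPR82 at 238 ± 81.9, MSC at 103 ± 60.2 and TLX1, a homeobox gene of spleen development, at 36.1 ± 10.6. Among the lists, 11 of 12 spleen and lymphocyte markers and 8 of 14 T and NK cell genes were called there. Lung carried surfactant and airway secretory transcripts. SFTPC was at 3081 ± 821 and SFTPB at 956 ± 131 in lung (SD, n = 8), against 1.09 ± 1.01 and 0.395 ± 0.718 in their nearest classes (n = 9). AGER, a receptor abundant in type I alveolar cells, was at 503 ± 74.6, SCGB3A1 at 249 ± 134, SCGB3A2 at 199 ± 99.0 and BPIFA1 at 148 ± 131. Of 13 lung markers 11 were called in lung.

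Kidney was marked by tubular transport genes. UMOD, uromodulin of the thick ascending limb, was at 1795 ± 191 scaled FPKM in kidney (SD, n = 9) and at 0.892 ± 2.01 in ovary (n = 9). The transporters SLC6A18, SLC5A12, SLC22A8 and SLC12A1 were at 229 ± 70.6, 224 ± 33.9, 220 ± 96.1 and 162 ± 27.7 in kidney, and TMIGD1 at 193 ± 39.3. Kidney carried 13 of 15 kidney markers. In skeletal muscle the contractile genes stood out: MYL11, a fast myosin light chain, was at 26098 ± 12067 (SD, n = 20), TNNC2, the fast troponin C, at 17092 ± 6723, MYL1 at 15616 ± 6993, SLN, a regulator of the calcium pump, at 7407 ± 2588, MYH8, the perinatal myosin heavy chain, at 4975 ± 1895 and MYOZ1 at 3426 ± 977. The nearest class for these 6 was subcutaneous adipose, with MYL11 at 224 ± 410 (n = 9). In that class MYL11 was at 1283 in the Meishan library and at a median of 45.9 in the others. In muscle 12 of 13 skeletal muscle markers, 11 of 12 fast fibre genes and 17 of 21 genes of glycolysis and glycogen were called. Slow fibre genes were divided, with 5 of 10 called in heart and 5 in skeletal muscle. Among those in heart, MYL3, a slow and ventricular light chain, was at 9262 ± 1370 (n = 9).

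Subcutaneous adipose was marked by adipocyte genes. PLIN1, the coat protein of adipocyte lipid droplets, was at 502 ± 84.6 scaled FPKM (SD, n = 9) and at 3.93 ± 3.36 in skeletal muscle (n = 20), ADIG, adipogenin, at 460 ± 102, TRARG1, a protein of glucose transporter traffic, at 282 ± 126, PAQR6 at 127 ± 49.2, SAL1 at 81.2 ± 60.3 and LGALS12 at 66.5 ± 33.6. Of the adipocyte markers 7 of 11 were called there, and so were 11 of 22 extracellular matrix genes, with POSTN at 547 ± 173 and COL1A2 at 1791 ± 797. Ovary held transcripts of the oocyte. DPPA5 was at 514 ± 216 (SD, n = 9) against 0.164 ± 0.277 in liver (n = 9), ZP3, a zona pellucida protein, at 345 ± 137, PADI6 at 145 ± 50.6, ZAR1 at 118 ± 39.7, FKBP6 at 115 ± 37.6 and KPNA7 at 89.0 ± 35.0. Ovary carried 13 of 15 ovary markers. The heatmap of mean levels shows 32 of these genes.

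**Figure D1:**
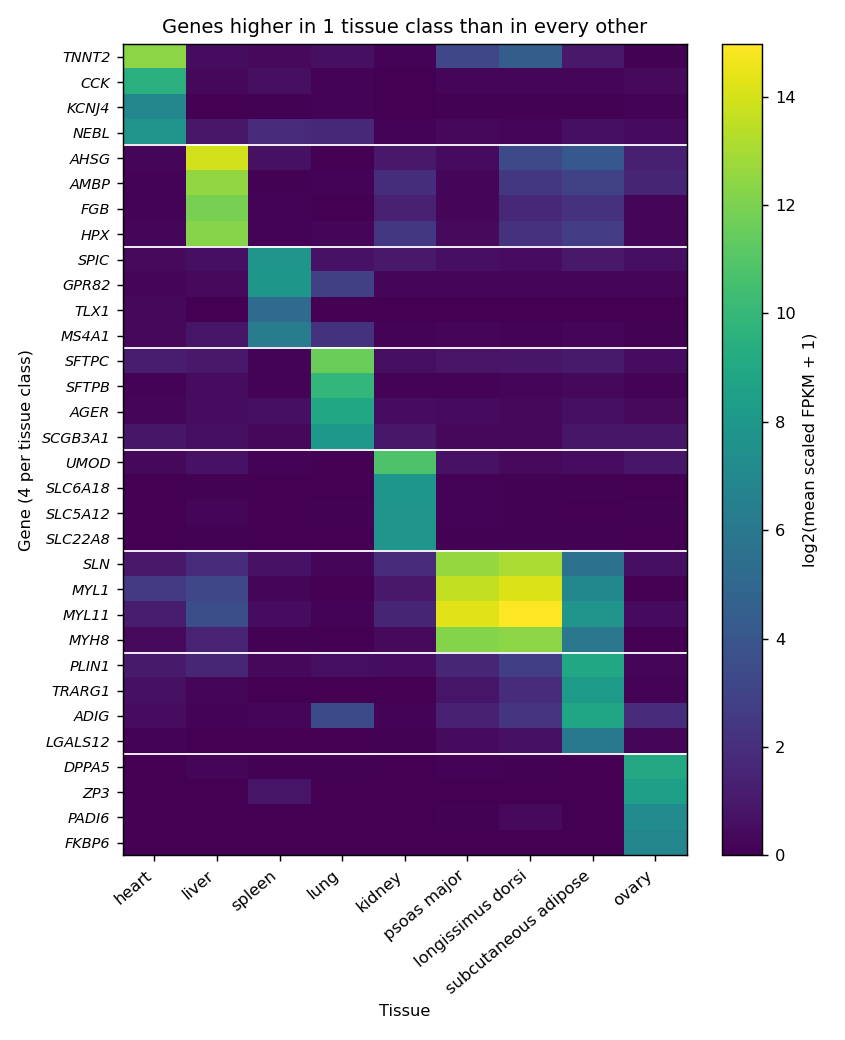
Heatmap of 32 genes (vertical) in 9 tissues (horizontal), coloured by log2 of mean scaled FPKM plus 1 over the libraries of a tissue. Each block of genes is brightest in its own tissue, such as UMOD at 1795 scaled FPKM in kidney and SFTPC at 3081 in lung.

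These calls needed a limma adjusted p under 0.05 and a log2 difference above 1 against every other class. In simulated data the same rule recovered 13.4% of genes raised 2-fold and 100% of those raised 4-fold, all with a mean level well above the filter.

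Psoas major, a deep loin muscle, was compared with longissimus dorsi, the long muscle of the back, in all 10 breeds. Psoas major carried more of the genes of fat oxidation and mitochondria, and longissimus dorsi more of those of fast fibres, glycolysis, extracellular matrix and ribosomes. For these lists adjusted p = 0.265 to 0.607 with an estimated correlation, so none of them held. Of 12112 genes, 1657 were higher and 1719 lower in psoas major, mostly by small amounts, with 33 and 67 past a log2 difference of 1 in size. HADHB, the thiolase subunit of mitochondrial beta oxidation, was at 193 ± 100 scaled FPKM in psoas major and 81.6 ± 15.8 in longissimus dorsi (SD, n = 10), 2.15-fold higher (log2 1.10 ± 0.21 SE, adjusted p = 0.00299) and higher in 10 of 10 breeds. PLIN5, a lipid droplet protein of oxidative tissue, was 2.24-fold higher in 10 of 10 breeds (1.17 ± 0.15). Some positional genes differed between the muscles: ZIC1, a transcription factor of dorsal mesoderm, was at 6.95 ± 1.85 in longissimus dorsi and 0.223 ± 0.189 in psoas major (log2 -2.68 ± 0.12, adjusted p = 2.79e-07), and HOXC6 at 9.90 ± 3.67 and 1.20 ± 0.298 (-2.25 ± 0.14), while HOXA10, a more posterior HOX gene, was at 0.580 ± 0.409 and 3.11 ± 0.931 (1.39 ± 0.10).

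Among the other genes that were higher in psoas major, TRNP1 reached 2.69-fold (log2 1.43 ± 0.18), IRX3 2.57-fold in 9 of 10 breeds, PRR32 2.43-fold, CLIP4 2.34-fold, PANK1, an enzyme of coenzyme A synthesis, 2.27-fold, CA2, a carbonic anhydrase, 2.19-fold and RCAN2 2.14-fold. PPP1R3G, a glycogen regulator, differed by a log2 of 1.14 ± 0.15. Those lower in psoas major included MSS51, a muscle mitochondrial regulator, at 7.06 ± 5.44 against 36.9 ± 21.5 (log2 -2.09 ± 0.30), POSTN, the matrix protein periostin (-1.41 ± 0.13), and ADAMTS8 (-1.32 ± 0.24), each in 10 of 10 breeds. Transcripts of liver plasma proteins were also lower in psoas major: ALB was at 1.17 ± 2.04 against 28.7 ± 32.6 in longissimus dorsi (-3.06 ± 0.61, adjusted p = 0.00598, 10 of 10 breeds). The same held for APOC3 (-2.48 ± 0.56), AHSG (-1.91 ± 0.37), APOE (-1.72 ± 0.27), TTR (-1.58 ± 0.40), TF (-1.41 ± 0.33) and AMBP (-1.37 ± 0.34), in 9 or 10 breeds.

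**Figure D2:**
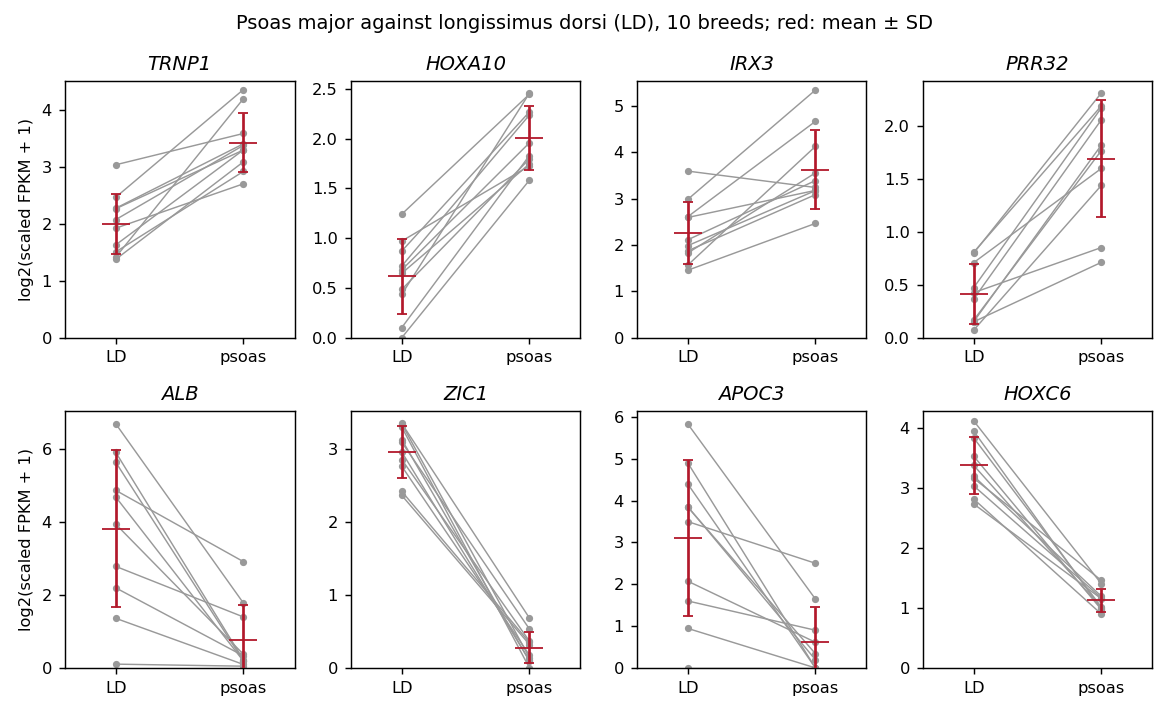
Paired levels of 8 genes in longissimus dorsi and psoas major of 10 breeds, on log2 of scaled FPKM plus 1, with grey lines joining the muscles of a breed and red points and bars giving the mean and SD. TRNP1, HOXA10, IRX3 and PRR32 are higher in psoas major, and ALB, ZIC1, APOC3 and HOXC6 are lower.

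By list, 15 of 28 moved against the other genes (camera, preset correlation), 7 up and 8 down in psoas major, and 0 of the 15 held with an estimated correlation. Fatty acid oxidation rose, with 15 of 20 genes higher (15 adjusted over the list alone) and ACAA2 at 1.99-fold, and red blood cell genes rose with 2 of 6 higher (3 adjusted over the list alone), namely CA2 and SPTB. Glycolysis and glycogen fell with 17 of 21 genes lower and 1 higher (18 and 2 adjusted over the list alone), GPI by 2.11-fold and PYGM, muscle glycogen phosphorylase, by 2.03-fold. Extracellular matrix fell with 18 of 22 lower (18 adjusted over the list alone), COL3A1 by 1.88-fold, and ribosomal proteins with 21 of 21 lower (21 adjusted over the list alone), RPS16 by 1.73-fold. Adipocyte markers fell with 5 of 9 lower (5 adjusted over the list alone), CIDEC by 1.86-fold and CFD by 1.76-fold. For these 6 lists the adjusted p was 0.265 with an estimated correlation. Fast fibre genes fell with 11 of 12 lower (12 adjusted over the list alone), TPM1 by 2.38-fold, and skeletal muscle markers with 8 of 13 lower and 1 higher (10 and 1 adjusted over the list alone), the higher gene being MYBPC1, a slow myosin binding protein. Genes of the mitochondrial genome rose, with 9 of 13 higher (9 adjusted over the list alone), ND5 by 1.89-fold. For these 3 lists adjusted p = 0.287 with an estimated correlation. The median of the mitochondrial list was 0.72 and its mean -1.19, since COX1 was listed at 0 in 4 psoas libraries and ATP6, ATP8 and COX3 in 5. Oxidative phosphorylation rose with 12 of 30 higher and 1 lower (15 and 1 adjusted over the list alone), the tricarboxylic acid cycle with 8 of 15 (10 adjusted over the list alone), PDHA1 by 1.55-fold, and heat shock and unfolded protein genes with 4 of 14 (4 adjusted over the list alone), HSPD1 by 1.57-fold. Adjusted p = 0.607 with an estimated correlation for these 3. Liver markers fell with 9 of 10 lower (10 adjusted over the list alone), at an adjusted p of 0.332 with an estimated correlation. Macrophage genes fell with 4 of 11 lower (6 adjusted over the list alone) and interferon genes rose with 3 of 19 higher (3 adjusted over the list alone), both at an adjusted p of 0.642 with an estimated correlation. Interferon and macrophage lists lost their call on deposited FPKM (adjusted p = 0.0573 and 0.0534). The interferon list also lost it without Bamei, Hampshire, Large White, Rongchang or Tibetan wild boar (0.0826, 0.0873, 0.0643, 0.0810 and 0.0890), the macrophage list without Berkshire, Jinhua, Piétrain or Rongchang (0.0802, 0.115, 0.0999 and 0.0842) and the heat shock list without Landrace or Rongchang (0.0691 and 0.0984). Slow fibre genes were not called, with 3 of 10 higher, 1 lower (3 and 1 adjusted over the list alone) and 6 not passing. HOX and positional genes went both ways, 4 of 12 higher and 4 lower (5 and 4 adjusted over the list alone), with a median of 0.07 and a mean of -0.25. Median and mean also differed in sign for spleen and lymphocyte markers and for fatty acid and triglyceride synthesis, neither of which was called.

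Without breed as a block, 350 genes were higher and 313 lower in psoas major, and TF lost its call. As deposited, 38.4% of the calls were higher, against 49.1% with scaling.

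Heart was compared with the mean of both skeletal muscles in 9 breeds. Contractile genes were exchanged: MYBPC3 was at 549 ± 113 scaled FPKM in heart (SD, n = 9) and 0.0683 ± 0.103 in skeletal muscle (n = 18), a log2 difference of 8.99 ± 0.07 (SE, adjusted p = 1.46e-25), and MYL11 was lower in heart by a log2 of -13.36 ± 0.27 (adjusted p = 8.04e-19), each in 9 of 9 breeds. Glycolytic genes were lower in heart, and markers of heart, cell division, interferon response and macrophages were higher. Of these lists only heart markers held with an estimated correlation, where adjusted p was 0.0534 for glycolysis, 0.425 for cell cycle and interferon response and 0.511 for macrophage genes. Of 12955 genes 5057 were higher and 3931 lower in heart, 867 and 843 of them by more than 1 on the log2 scale.

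Structural and junction genes of the myocardium were higher in heart in 9 of 9 breeds: TNNT2 (log2 8.71 ± 0.26), NEBL (7.12 ± 0.06), RYR2, the calcium release channel of heart (5.55 ± 0.06), CDH2, the cadherin of the intercalated disc (7.18 ± 0.30), and PKP2, a desmosomal plaque protein (5.11 ± 0.06). PYGB, the brain form of glycogen phosphorylase, differed by 7.36 ± 0.09, CCK by 8.73 ± 0.18, KCNJ4 by 6.32 ± 0.12, SERPINB2 by 5.69 ± 0.12, TSPAN12 by 5.14 ± 0.21 and B3GALT2 by 5.04 ± 0.17. Lower in heart in 9 of 9 breeds were TNNC2 (-12.52 ± 0.23), SLN (-11.56 ± 0.15), MYH8 (-11.46 ± 0.20), MYL1 (-11.42 ± 0.23), ATP2A1, the calcium pump of fast fibres (-10.81 ± 0.13), MYOZ1 (-10.46 ± 0.12), MYBPC2 (-9.68 ± 0.19), MYBPC1 (-9.51 ± 0.08), CA3, a muscle carbonic anhydrase (-9.31 ± 0.34), TMOD4 (-8.25 ± 0.11) and MYBPH (-8.18 ± 0.38). MYF6 and MYOD1, myogenic factors at 154 ± 93.7 and 28.4 ± 13.9 in skeletal muscle, were listed at 0 in all 9 hearts.

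Of 29 lists, 13 moved against the other genes, 6 up and 7 down in heart. The 4 that held with an estimated correlation were heart markers, 9 of 9 higher (9 adjusted over the list alone), skeletal muscle markers, 12 of 13 lower and 1 higher (12 and 1 adjusted over the list alone), the higher gene being ACTA1, listed at 0 in 9 of 10 longissimus dorsi and 6 of 10 psoas major libraries, myogenic and growth regulators, 9 of 14 lower and 1 higher (9 and 1 adjusted over the list alone), and HOX and positional genes, 12 of 14 lower and 2 higher (12 and 2 adjusted over the list alone), including HOXA7 (log2 -3.03 ± 0.12). TBX5, a cardiac and forelimb factor of that list, was higher in heart (3.85 ± 0.09). Fast fibre genes fell with 12 of 12 lower (12 adjusted over the list alone), at an adjusted p of 0.0830 with an estimated correlation. Glycolysis and glycogen fell with 20 of 21 lower and 1 higher (20 and 1 adjusted over the list alone), LDHA by 43.0-fold and PYGM by 45.7-fold, at an adjusted p of 0.0534 with an estimated correlation. Adipocyte markers fell with 8 of 9 lower (8 adjusted over the list alone), among them PNPLA2, the triglyceride lipase, by 2.60-fold, at an adjusted p of 0.110 with an estimated correlation. Cell cycle genes rose with 17 of 18 higher (17 adjusted over the list alone), CDK1 at 10.6 ± 8.26 against 2.95 ± 2.51. Interferon response rose with 20 of 20 (20 adjusted over the list alone), RSAD2 by 1.85-fold, antigen presentation with 7 of 7 (7 adjusted over the list alone), and T and NK cell genes with 11 of 12 higher and 1 lower (11 and 1 adjusted over the list alone). For these 4 lists adjusted p = 0.425 with an estimated correlation. Macrophage genes rose with 11 of 11 higher (11 adjusted over the list alone), CTSS by 2.22-fold, at an adjusted p of 0.511 with an estimated correlation. Ribosomal proteins fell with 12 of 21 lower and 2 higher (12 and 2 adjusted over the list alone), at an adjusted p of 0.897 with an estimated correlation. Not called were fatty acid oxidation, 8 of 20 higher and 5 lower (8 and 5 adjusted over the list alone), and oxidative phosphorylation, 14 of 30 higher and 3 lower (11 and 3 adjusted over the list alone). Median and mean, or mean and test, differed in sign for fatty acid oxidation, fatty acid and triglyceride synthesis, cholesterol synthesis and red blood cell genes, all without a call.

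On deposited FPKM 7974 genes were higher and 1962 lower in heart, with the median of all genes at 0.32 in place of 0.05, and the T and NK cell list lost its call (adjusted p = 0.0841). After quantile normalization the ribosomal list pointed up (adjusted p = 0.178) and the oxidative phosphorylation list was called (adjusted p = 0.000266).

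The breeds were compared by origin on the mean log2 level over 8 tissues, with 4 Chinese breeds (Bamei, Jinhua, Meishan and Rongchang) and the 5 Western breeds. Few genes differed: of 16996 tested, 30 were higher and 21 lower in the Chinese breeds, and 16 of these 51 had a symbol. SNCG, gamma-synuclein, on chromosome 14, was lower, at 0.801 ± 0.153 scaled FPKM in Chinese and 10.9 ± 2.84 in Western breeds (SD, n = 4 and 5), a log2 difference of -2.52 ± 0.17 (SE, adjusted p = 0.000443). That gene was lower in the Chinese breeds in 9 of 9 tissues and passed the test in 6 of them taken alone, with an interaction of tissue and origin (adjusted p = 0.0246). BEX1, a small X-linked gene of nerve growth factor signalling, was at 17.3 ± 1.86 against 28.4 ± 1.25 (-1.07 ± 0.12, adjusted p = 0.00531), lower in 9 of 9 tissues and passing in 2 of them. Its difference ranged from -2.06 in liver to -0.22 in kidney (adjusted p = 0.467), with an interaction of tissue and origin (adjusted p = 0.000185). GBP1, an interferon-induced GTPase, was higher in the Chinese breeds, at 2.27 ± 0.536 against 0.624 ± 0.380 (0.93 ± 0.11, adjusted p = 0.00675), in 5 of 5 tissues tested, passing in 3.

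MAMDC4 was 1.80-fold lower in Chinese breeds (adjusted p = 0.00351), ATPAF2, an assembly factor of ATP synthase, 1.71-fold lower (0.0215) and APOOL, a protein of mitochondrial cristae, 1.67-fold lower (0.0102), each in 9 of 9 tissues and passing in 3, 1 and 2 of them, while GLYATL2 was at 0.0708 ± 0.0515 against 1.10 ± 0.738 (adjusted p = 0.0306). Higher in Chinese breeds on the log2 mean were GCNT3, a mucin glycosyltransferase, 1.52-fold (adjusted p = 0.00675), NUDCD1 1.51-fold (0.0407), SYP, synaptophysin of vesicles, 1.42-fold (0.0142), NECTIN1, a cell adhesion protein, 1.33-fold (0.00436), RNF169 1.32-fold (0.0112), ICE2 1.28-fold (0.0400) and BEX5 1.23-fold (0.00708). The folds of genes at low level depended on the 1 added before the logarithm. NECTIN1 was at 0.484 ± 0.148 scaled FPKM in Chinese and 0.0143 ± 0.0110 in Western breeds (SD, n = 4 and 5), and BEX5 at 0.614 ± 0.150 and 0.126 ± 0.0510. With a pseudocount of 0.1 the log2 difference was 1.39 for NECTIN1, 0.91 for BEX5, 1.18 for GCNT3, 1.16 for SYP, 0.61 for RNF169 and 0.46 for ICE2. NUDCD1, RNF169 and ICE2 were higher in 9 of 9 tissues, SYP in 4 of 4, NECTIN1 in 2 of 2 and BEX5 in the 1 tested, and of these only NECTIN1 passed in a single tissue. GCNT3 was higher in 4 of 5 tissues with a smallest adjusted p of 0.0829 in heart, was lower in spleen (log2 -0.19 ± 0.16), and was among the genes with an interaction of tissue and origin (adjusted p = 0.0254). Of the genes named BEX1, APOOL, BEX5 and SYP lie on chromosome X. Some alternatives ended calls, with log2 differences given as the range over all alternatives. ATPAF2 lost its call without Berkshire, Large White or Meishan (-0.85 to -0.69). GLYATL2 lost it without any breed but Berkshire or Piétrain, without the trend and robust options and with all 10 breeds in a duplicateCorrelation fit (-1.11 to -0.37). NUDCD1 lost it without any breed but Large White or Meishan, with a pseudocount of 0.1 and with no filter on low values (0.53 to 0.77), and ICE2 without any of the 9 and after quantile normalization (0.32 to 0.46).

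**Figure D3:**
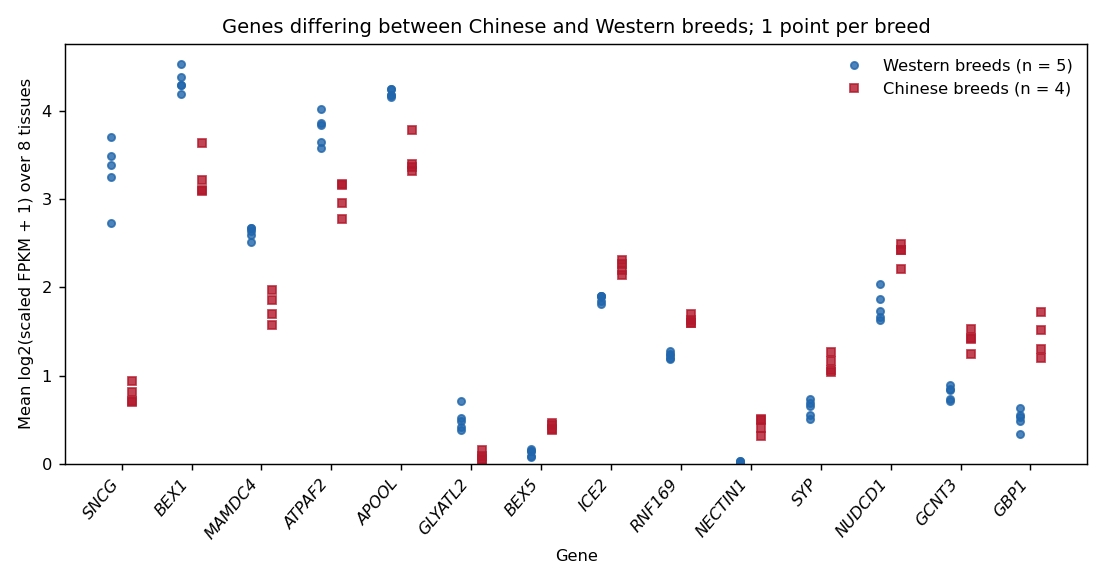
Mean log2 of scaled FPKM plus 1 over 8 tissues for 14 genes, 1 point per breed, with 5 Western and 4 Chinese breeds side by side. Groups are furthest apart for SNCG and BEX1, with log2 differences of -2.52 and -1.07.

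Of 37 lists 2 were called for origin. Brain and nerve markers were higher in the Chinese breeds with 2 of 11 genes passing (3 adjusted over the list alone), SYP among them, and adjusted p = 0.719 with an estimated correlation. The tricarboxylic acid cycle list was lower with 0 of 15 genes passing (1 adjusted over the list alone), PDHB having a log2 difference of -0.15 ± 0.08, and adjusted p = 0.970 with an estimated correlation. That list lost its call on deposited FPKM (0.140), after quantile normalization (0.173) and without Landrace, Bamei or Rongchang (0.173, 0.0892 and 0.239). Interferon response had 1 of 20 genes passing (1 adjusted over the list alone), GBP1, and was not called. Median, mean and test differed in sign for 9 lists, none of them called: liver, adipocyte and pancreas markers, fast fibre genes, glycolysis, myogenic regulators, neutrophil genes, ribosomal proteins and the circadian clock.

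The groups hold 4 and 5 breeds, and each breed is 1 library per tissue. The values of each breed were deposited separately, so every comparison by origin runs between separate deposits. Whether their processing differed was not tested. With all tissue libraries of 10 breeds and a within-breed correlation of 0.156, limma called 161 genes higher and 239 lower. That fit counts the tissues of a breed as separate libraries, with 1 correlation for all genes, so its counts may be too high. On the means over 8 tissues, 17 genes were higher without Piétrain.

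Within single tissues, 27 genes differed by origin in heart, 16 in liver, 23 in lung, 30 in kidney, 2 in psoas major, 5 in longissimus dorsi, 12 in subcutaneous adipose and 11 in ovary. In spleen limma called 0 of 13160 genes, with 670 at an unadjusted p under 0.05. SNCG passed in 6 of these tissues, among them subcutaneous adipose (log2 -3.05 ± 0.28), heart (-2.91 ± 0.23) and ovary (-2.65 ± 0.23). In liver, PPP1R1B, a phosphatase inhibitor, was 4.47-fold higher in Chinese breeds (n = 4 and 5, log2 2.16 ± 0.18 SE, adjusted p = 0.00211), and BEX1 was at 6.22 ± 1.78 and 29.6 ± 8.21 (SD). Kidney showed lower ITIH1 at 0.0884 ± 0.0846 against 4.59 ± 1.51, higher RND2 at 9.60 ± 2.70 against 2.94 ± 0.498, and NECTIN1, at 1.92 in the Chinese breeds and listed at 0 in all 5 Western breeds. The Chinese hearts had less PDK1, a kinase that restrains pyruvate dehydrogenase, at 14.8 ± 0.929 against 23.5 ± 0.727 (log2 -0.64 ± 0.07), less APOOL at 21.8 ± 3.18 against 42.0 ± 2.70, less MAMDC4 at 1.33 ± 0.291 against 3.29 ± 0.325 and more LRRC23 at 1.74 ± 0.501 against 0.298 ± 0.123. Lungs of the 3 Chinese breeds had more GBP1 (1.88 ± 0.17) and ARMCX2 (1.62 ± 0.19) and less BEX1 (-0.90 ± 0.09) and MAMDC4 (-0.84 ± 0.09). In subcutaneous adipose DCLK3 (-2.07 ± 0.28) was lower and PCDHAC2 (1.16 ± 0.16) was higher. Ovaries of Chinese breeds had less CCN2, a matricellular growth factor, at 6.08 ± 1.51 against 23.6 ± 4.93 (-1.80 ± 0.19), and less ITM2A at 16.3 ± 3.91 against 37.1 ± 3.50.

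Several single-tissue calls rested on particular breeds or processing choices, with ranges of log2 over all alternatives. In heart MAMDC4 lost its call without Piétrain (-1.26 to -0.84) and LRRC23 without Hampshire, Landrace, Large White, Piétrain or Bamei (0.95 to 2.22). In liver BEX1 lost it without Landrace or Rongchang (-2.26 to -1.98). In lung BEX1 lost it without Bamei or Meishan (-0.97 to -0.83), ARMCX2 without Bamei, Jinhua or Meishan (at most 1.77) and MAMDC4 without these or Berkshire (-1.07 to -0.80). In subcutaneous adipose DCLK3 lost it without any breed but Hampshire or Piétrain, with no filter on low values and with a filter of 5 FPKM (-2.94 to -1.87). PCDHAC2 lost it without any breed but Piétrain, after quantile normalization, with a pseudocount of 0.1 and with no filter, and kept it in 3 of 14 alternatives (1.02 to 1.77). ITM2A in ovary lost it without any breed but Bamei or Meishan and with no filter (-1.28 to -1.04). Counts of different tissues were not tested against each other. Leaving out 1 breed moved the counts: 64 genes passed in ovary without Meishan, whose ovary correlated least with its tissue, 36 in spleen without Berkshire, 4 in liver without Landrace and 11 in heart without Piétrain. In simulated data the test in liver recovered 17.9% of genes changed 1.5-fold, 73.1% at 2-fold and 93.9% at 4-fold, and the test in spleen 37.3%, 73.1% and 92.4%. The other 7 tissues were not simulated, and neither were changes in genes at low level.

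Whether the tissue profile itself differed by origin was tested with an interaction of tissue and origin. Of 16996 genes 423 passed, a count for which chance was not excluded. The test takes 1 spread per gene for all tissues. Its p can therefore be too small for a gene that lies near 0 in most of them. NECTIN1 was at 1.81 ± 0.735 scaled FPKM in liver and 1.59 ± 0.393 in kidney of Chinese breeds (SD, n = 4), at 0.0980 ± 0.0722 in Western livers and listed at 0 in Western kidneys (n = 5, adjusted p = 4.63e-18). NPC1L1, the sterol transporter of the bile canaliculus, was at 8.37 ± 4.80 in Chinese and 1.53 ± 0.413 in Western livers, and SLC5A9, a mannose transporter, at 5.65 ± 2.73 and 0.653 ± 0.571. In subcutaneous adipose ATP6V0A4, a proton pump subunit, was at 1.85 ± 3.54 in Chinese and 19.9 ± 9.43 in Western breeds, against 18.2 ± 1.80 and 14.2 ± 3.14 in kidney. DCLK3 was at 0.751 ± 0.300 and 6.47 ± 2.97 and GLYATL2 at 0.381 ± 0.448 and 7.83 ± 5.93 in the same fat samples. BEX5 differed mainly in ovary (4.05 ± 1.33 and 1.01 ± 0.408) and SPIRE2 in heart (17.4 ± 5.46 and 4.36 ± 2.02). NAP1L3 was higher in Chinese breeds in subcutaneous adipose (6.36 ± 3.07 and 2.40 ± 0.401, log2 1.04) and kidney (7.13 ± 0.578 and 4.04 ± 0.804, log2 0.70). It was lower in spleen (log2 -0.45), ovary (-0.40) and liver (-0.33). The count moved to 782 without Meishan, 268 without Landrace and 197 with a pseudocount of 0.1. For the psoas minus longissimus difference, limma called 0 of 12112 genes by origin, the smallest adjusted p being 0.577 and 596 genes being at an unadjusted p under 0.05. That test recovered 43.9% of genes changed 4-fold in simulated data, all with a mean level well above the filter.

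The mixtures were compared with the mean of the 9 tissues of the same breed in 8 breeds. Both skeletal muscles entered that mean, so muscle genes weigh more in it than genes of another single tissue. Most brain and nerve, liver and kidney markers were higher in the mixtures, and most ovary and skeletal muscle markers were lower. GFAP, the filament protein of astrocytes, was at 71.1 ± 36.8 scaled FPKM in mixtures and 0.674 ± 0.216 in the tissue mean (SD, n = 8, log2 5.26 ± 0.30 SE, adjusted p = 3.43e-06), and SNAP25, of the synaptic fusion complex, at 39.7 ± 16.5 and 0.305 ± 0.231, each in 8 of 8 breeds. Of 17284 genes 3630 were higher and 7010 lower in the mixtures, and 114 were in every mixture above every tissue library.

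Further neural genes were higher in 8 of 8 breeds: TUBB4A (log2 4.57 ± 0.29), TUBB3 (3.99 ± 0.25), SLC17A7, a vesicular glutamate transporter (3.87 ± 0.22), MAG, a myelin glycoprotein (3.82 ± 0.27), FABP7 of glia (3.71 ± 0.23), NRSN1 (3.70 ± 0.25) and KIF5A (3.59 ± 0.19), with FBXL16 higher too. Brain and nerve markers were higher for 14 of 15 genes (14 adjusted over the list alone). Oocyte and other ovary genes were lower: DPPA5 was at 0.151 ± 0.158 in mixtures and 58.3 ± 26.1 in the tissue mean (-5.52 ± 0.91), ZP3 differed by -4.96 ± 0.68, PADI6 by -3.94 ± 0.41, ZAR1 by -3.73 ± 0.38, KPNA7 by -3.15 ± 0.28 and INHA, the inhibin alpha chain, by -3.63 ± 0.36, and FKBP6 was listed at 0 in all 8 mixtures. Against the mean of log2 values these differences shrank to -0.86 for DPPA5, -0.81 for ZP3, -0.81 for PADI6, -0.75 for ZAR1, -0.60 for KPNA7 and -0.71 for INHA, all still called. PLIN1 (-3.18 ± 0.27) and TRARG1 (-3.04 ± 0.30) were lower against the mean of the tissues and turned to 0.79 and 0.68 against the mean of their log2 values. MRC2 (-7.73 ± 3.04), SNORA2C (-3.77 ± 0.71) and SNORA21, listed at 0 in all 8 mixtures, were lower but had zeros beside values above 100 FPKM in a tissue, and MRC2 lost its call without Berkshire, Large White, Piétrain or Bamei (log2 -8.12, -7.32, -8.41 and -7.25). SNORA2C lost its call against the mean of log2 values (-0.94).

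Relative to their own tissue, the median gene called in liver was at 28.9% in the mixtures, ranging from 24.2% to 35.9% between breeds, that of kidney at 25.2%, of spleen at 23.3%, of lung at 22.9%, of heart at 12.1%, of ovary at 11.5%, of subcutaneous adipose at 9.21% and of skeletal muscle at 9.09%. Liver markers were higher than the tissue mean for 17 of 18 genes (17 adjusted over the list alone), kidney markers for 14 of 15 (14 adjusted over the list alone) and cholesterol synthesis for 16 of 18 (16 adjusted over the list alone). Ovary markers were lower for 13 of 15 (14 adjusted over the list alone), skeletal muscle markers for 12 of 13 (12 adjusted over the list alone), heart markers for 8 of 9 (8 adjusted over the list alone), and oxidative phosphorylation for 29 of 30 (30 adjusted over the list alone). Pancreas markers were below the tissue mean for 5 of 5 genes (5 adjusted over the list alone).

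**Figure D4:**
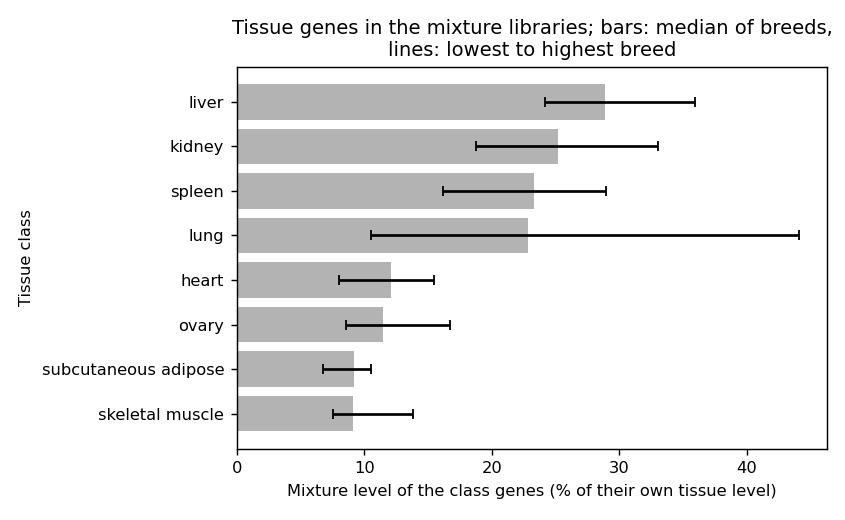
Median level in the mixtures of the genes called in each tissue class, as a percentage of their level in that tissue (bars), with lines from the lowest to the highest of 8 breeds. Liver, kidney, spleen and lung lie between 22.9% and 28.9%, and heart, ovary, subcutaneous adipose and skeletal muscle between 9.09% and 12.1%.

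Against the mean of log2 values 6482 genes were higher and 4571 lower in the mixtures, after quantile normalization 1717 and 12521. The median of all genes was -0.08 with scaling, -0.13 on deposited FPKM and -0.38 after quantile normalization. In simulated data 25.4%, 41.8% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, all with a mean level well above the filter.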

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

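The tests of a mislabelled sample, of reads lost on the reference, of chromosome X and of all splits of the libraries were chosen only after the result was seen.

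Some libraries stood apart from the others of their tissue, in part by small margins. The median Spearman correlation with the own tissue was 0.957 for the Hampshire spleen (others 0.961 to 0.965), 0.953 for the Bamei lung (0.958 to 0.961) and 0.911 for the Meishan ovary (0.946 to 0.962). Total FPKM was 2196140 in the Large White heart (others 860191 to 1511960), 1008120 in the Landrace liver (588906 to 715833), 1370460 in the Piétrain kidney (781589 to 1028890), 519075 in the Tibetan wild boar psoas major (846662 to 1082120), 942855 in the Jinhua longissimus dorsi (700256 to 804321) and 1221010 in the Meishan ovary (586167 to 744497). The 10 most abundant genes held 74.4% of the total in that heart, 47.2% in that liver, 65.8% in that kidney and 58.1% in that ovary. The medians of these tissues were 46.2%, 21.9%, 47.1% and 22.2%. Among named genes, CA3 in Landrace had a heart minus muscle log2 difference of -6.41 (other breeds -10.61 to -8.83), and APOOL in Rongchang a mean log2 level of 3.79 (other Chinese breeds 3.32 to 3.40). The Meishan mixture stood apart for TUBB3 at 2.48 (others 3.87 to 4.64) and ZAR1 at -2.01 (-4.23 to -3.56). Of 123 groups tested, 13 held such a value, where chance alone gives about 5%.

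The tissue profile differed by origin for 423 genes by an interaction test, with adjusted p (limma) of 4.63e-18 for NECTIN1, 2.26e-11 for NPC1L1, 1.51e-10 for ATP6V0A4, 2.53e-09 for SLC5A9, 4.36e-09 for BEX5, 1.32e-08 for DCLK3, 4.58e-08 for NAP1L3, 6.71e-08 for GLYATL2 and 1.31e-07 for SPIRE2. Of 100 splits of the breeds into groups of 4 and 5, 7 gave as many genes, the highest other 3909, so chance cannot be excluded for the count. That split set Hampshire, Piétrain, Bamei and Jinhua against the other breeds. A split with several times the real count points to a structure of the samples, but the next splits, at 1698 and 1662, grouped the breeds differently, and whether a few libraries set these counts was not tested.

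Other splits of the same libraries were counted for each comparison, the real split included. For the tissue classes 1 of 100 splits gave as many genes in each case: heart 220, liver 782, spleen 460, kidney 479, skeletal muscle 375 and subcutaneous adipose 288 had a highest other of 0, lung 299 of 1 and ovary 1047 of 159, so chance is excluded. Between the muscles the 1657 higher and 1719 lower genes were reached by 1 of 100 splits each (highest other 74) and the 15 lists by 2 of 100 (highest other 15). For heart the 5057 higher and 3931 lower genes were reached by 1 of 100 (highest other 2424 and 3362), while the 13 lists were reached by 40 of 100 (highest other 21), so chance is not excluded for the number of lists. By origin, the 30 higher genes were reached by 1 of 100 (16), the 21 lower genes by 2 of 100 (86) and the 2 lists by 99 of 100 (17), so chance is not excluded for the lists. Within tissues, few splits reached the count for heart (27 genes, 2 of 100, highest other 65), liver (16, 3 of 100, 917), lung (23, 1 of 56, 3) and kidney (30, 1 of 100, 8). The same held for longissimus dorsi (5, 2 of 100, 78), subcutaneous adipose (12, 2 of 100, 1030) and ovary (11, 1 of 100, 3). More splits reached it for psoas major (2, 5 of 100, 3) and spleen (0, 100 of 100, 7). These shares were not corrected for the 9 tissues, so chance is not excluded for the count of any single tissue. The highest splits of liver, subcutaneous adipose and longissimus dorsi, and of the lower genes by origin, gave several times the real count, which points to a structure of the samples. What that structure is, or whether single libraries make it, was not tested. The psoas minus longissimus difference by origin, 0 genes with limma and 596 at an unadjusted p under 0.05, was reached by 100 of 100 splits (highest other 3). The 3630 genes higher and 7010 lower in the mixtures were reached by 1 of 100 splits each (highest other 1886).

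Liver transcripts were higher in longissimus dorsi than in psoas major, with a psoas minus longissimus log2 difference of -3.06 for ALB. For 65 genes at 1000 FPKM or more in liver, the difference was a median of 0.0719% of the liver level, above 0 for 61, with an upper quartile 1.59 times the lower. Liver RNA carried into the longissimus dorsi libraries may therefore be the source, as it needs a single share for all genes. Such transcripts were not limited to that muscle: the median level of the 65 genes was 0.0887% of liver in longissimus dorsi, 0.0106% in psoas major, 0.128% in subcutaneous adipose (lower quartile 0.109%) and 0.146% in kidney (lower quartile 0.0118%), and the source in these tissues was not tested. As the source of the liver transcripts, adipose tissue in the muscle is argued against. The difference between the muscles came to 50.7% of the adipose level for the liver genes and 3.13% for 79 adipose genes, a ratio of 16.2. Of these 79 genes 72 were higher in longissimus dorsi, so more adipose tissue in that muscle stays open and was not tested. The median level of the 65 genes was 10.4 in longissimus dorsi and 0.296 in psoas major of Piétrain but 0.0699 and 0.105 in Tibetan wild boar, and a biological difference between the muscles stays open and was not tested.

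The Meishan subcutaneous adipose library held muscle transcripts. For 33 muscle genes at 1000 FPKM or more the excess over the other fat libraries was a median of 5.07% of the Meishan muscle level, above 0 for 31 (TNNI1 and TNNT1 were the exceptions), with an upper quartile 1.66 times the lower, and the median was -0.163% to 0.780% in other breeds. Skeletal muscle in the dissected fat may be the source. A mislabelled sample is argued against, since its 8 most similar libraries were the 8 other adipose libraries, the nearest being Landrace at 0.950, and 1 of 11 adipocyte markers lay below all others. No biological explanation was tested.

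For the genes that differ by origin over 8 tissues, reads of the Chinese breeds lost on the reference are argued against as the only source, since lost reads lower a gene and 58.8% of all 51 genes were higher in those breeds. They may still act on single genes. For the 21 lower genes the question cannot be told apart from true expression: the log2 ratio ranged over a median of 0.69 between tissues, but only 8 of the 21 had enough tissues to be measured. Chromosome X held 5 of 15 located genes (among them BEX1, APOOL, BEX5 and SYP) against 3.83% of tested genes, a permutation p of 0.0004 over 10000 draws. The draws took genes as independent, so that p does not allow for neighbouring genes that differ together. It may be that chromosome X differs more between the breed groups than other chromosomes, a hypothesis found and tested on the same data. Differences in breed, rearing, sampling or the processing of the separately deposited breeds stay open as untested explanations.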

How the results depend on the processing

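Leaving out genes with conflicting zeros, the Meishan ovary, the Meishan subcutaneous adipose library or the genes called in liver was chosen only after the result was seen. Of 516 alternative counts 426 were within 1.5 times the reported count and 90 were not. Of 1293 alternative list tests 1219 kept their side of the threshold, 48 lost a call, 25 gained it and 1 reversed. Of 173 results of named genes, each a gene in 1 comparison, 150 kept their call in every alternative that tested the gene. Of the others 21 lost it in 1 or more and 2 reversed. Not every alternative tested each gene, and the filter at 5 FPKM tested 158 of the 173. A gene named in several comparisons counts in each, and genes not reported here are included. Where no cause is given below, the cause was not tested.

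On FPKM as deposited, heart had 7974 higher and 1962 lower genes, the tissue classes liver 487, skeletal muscle 212 and ovary 1773, origin 1 list, and the variance shares were 88.1% for tissues and 2.94% for breeds. After quantile normalization the mixtures had 1717 higher and 12521 lower genes, longissimus dorsi 2 genes by origin, origin 1 list, and the ribosomal list in heart reversed (adjusted p = 0.178). A pseudocount of 0.1 gave 197 tissue profiles, 6 genes in liver, 2 in longissimus dorsi, 7 in subcutaneous adipose and 4.35% for breeds. Without a filter there were 5 genes in psoas major and 11 in longissimus dorsi, with shares of 77.9% and 5.27%. A filter at 5 FPKM, which tests fewer genes, gave 1053 higher genes in psoas major, 3259 in heart, 262 tissue profiles, shares of 85.2% and 3.79%, and by origin 7 genes in heart, 5 in liver, 14 in lung, 15 in kidney, 1 in psoas major, 1 in longissimus dorsi, 1 in subcutaneous adipose and 7 in ovary. Without breed as block the muscles differed in 350 and 313 genes. A log2 difference above 2, stricter by construction, left 86 genes for heart, 400 for liver, 105 for spleen, 89 for lung, 202 for kidney, 146 for skeletal muscle, 93 for subcutaneous adipose and 348 for ovary. With an estimated correlation 0 lists were called between the muscles, 4 in heart and 0 by origin. All tissue libraries with a within-breed correlation gave 161 higher and 239 lower genes by origin, counts that may be too high because tissues of a breed enter as separate libraries. Leaving out conflicting zeros left 3 genes in longissimus dorsi, and without Tibetan wild boar psoas major had 8. Against the mean of log2 values the mixtures had 6482 higher and 4571 lower genes, and PLIN1 and TRARG1 reversed to 0.79 and 0.68, since that mean gives a gene of 1 tissue less weight.

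Leaving out 1 breed at a time, genes higher by origin ranged from 17 (without Piétrain) to 28, lists by origin from 1 to 8 (without Jinhua), tissue profiles from 268 to 782, variance shares from 83.1% to 84.2% and from 3.72% to 4.14%. By origin within tissues the ranges were 11 to 21 in heart, 4 to 14 in liver, 0 to 36 in spleen, 10 to 24 in lung, 14 to 37 in kidney, 0 to 8 in psoas major, 2 to 9 in longissimus dorsi, 6 to 15 in subcutaneous adipose, 6 to 64 in ovary and 0 to 1 for the psoas minus longissimus difference. Absolute depth is unknown, and relative depth differed by at most 1.97-fold between libraries.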

Other observations

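The values here are those of lists and libraries outside the main comparisons, and no explanation was tested in this part.

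Immune transcripts divided between spleen, lung and liver. In spleen POU2AF1, a B cell coactivator, was at 46.1 ± 12.6 scaled FPKM (SD, n = 10), MZB1 of plasma cells at 116 ± 49.9, LCK, a T cell kinase, at 55.2 ± 11.4 and CD247 at 112 ± 19.1. Macrophage genes were called once in liver (CD14, 460 ± 114, n = 9), once in spleen (CSF1R) and 2 times in lung, where MARCO, a scavenger receptor of alveolar macrophages, was at 592 ± 123 and LYZ at 335 ± 256 (n = 8), out of 12. Lung also carried 7 of 18 immediate early genes, with EGR1 at 116 ± 47.4, JUNB at 108 ± 49.6 and FOS at 147 ± 87.7. Red blood cell genes were called in spleen for 3 of 12, including HBB at 4496 ± 2820, in kidney for 2 and in skeletal muscle for 1.

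Fatty acid oxidation had 3 of 20 genes called in liver (ACSL1 at 1042 ± 474, n = 9) and 1 in skeletal muscle, and fatty acid and triglyceride synthesis 3 of 16 in liver (FADS2 at 334 ± 144), 3 in subcutaneous adipose (FASN at 153 ± 200) and 1 in kidney. HOX and positional genes had 5 of 18 called in kidney (HOXB6 at 19.8 ± 4.42, HOXA10 at 8.36), 2 in skeletal muscle and 1 in lung (TBX4 at 23.0 ± 3.61). Myogenic and growth regulators had 5 of 14 in skeletal muscle (MYF6 at 212 ± 123) and 2 in subcutaneous adipose (IGF1 at 32.4). No gene was called for a tissue class in the lists of oxidative phosphorylation (30 genes), tricarboxylic acid cycle (15), ribosomal proteins (21), interferon response (20), mitochondrially encoded genes (13) and smooth muscle and endothelium (12).

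Libraries of the same breed shared a small part of their variation across tissues. After removal of tissue means, the correlation of a breed's libraries averaged 0.116 to 0.409 over 28 tissue pairs, with a median of 0.172, and 219 of 252 same-breed pairs were above 0.1. The labels do not say whether these libraries came from 1 animal.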
